A study of Mus musculus with 9 samples.

How the data were processed

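RNA of 3T3-L1 adipocytes was hybridized to Affymetrix mouse expression arrays, 1 array per sample, with 3 groups of 3. Total RNA was extracted with Trizol and labelled as biotinylated cRNA, per the labels' protocols. The deposited values are log2 expression values per probe set, made with RMA (background correction, normalization between arrays and summary over probes) in R 2.9.0, per the submitters' processing notes. The authors also deposited tables of their comparisons made with limma, which hold log2 fold changes, a score for each probe set (moderated t and log odds) and p-values with adjusted p-values, per the file headers. Which version of limma they used is not given in the sources used here. The values were not normalized again except in the alternatives. Medians of the 9 arrays lay between 5.02 and 5.14. Their 99th percentiles lay between 11.63 and 12.48, so the ranges of the deposited values were not equal between arrays.

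Of 45101 probe sets, 64 controls were left out of the tests, which leaves 45037. Of these, 34945 had 1 gene symbol, 932 had several and 9160 had none here, by the array annotation used. Entrez IDs of 34741 probe sets were found in the gene table, and 0 symbols changed through them. Only probe sets with a single symbol were named, and the probe set with the highest mean over all arrays stood for its gene, which gave 18193 genes. The 25 gene lists held 410 entries, of which 382 matched a measured gene, 3 of them through an older symbol. The others are not analysed here. No gene was in more than 1 list.

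Each comparison was a contrast in a single limma fit (lmFit and eBayes, limma 3.58.1, R 4.3.3) over all 9 arrays and 3 groups, two-sided, with Benjamini-Hochberg adjustment over 45037 probe sets and a threshold of 0.05. Counts adjusted over the list alone adjust within the list's members. Lists were tested with camera at a preset correlation of 0.01, adjusted over 75 tests (25 lists in 3 comparisons), with an estimated correlation and fry as alternatives. The groups, tests, lists and naming rule were fixed before the data were examined. Per comparison the text names genes by that rule: the 10 largest rises and 10 largest falls among called genes with no overlap between the arrays of the groups (chance gives non-overlap for 10% of genes with 3 against 3), up to 4 members per list with the smallest adjusted p, and 15 genes always. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so single genes were tested with limma, which shares the spread across genes. By a rule added after the data were seen, the brightest probe set was taken as not above background in a group where every array had it at or under the 95th percentile of 27 probe sets of the control transcripts dap, lys, phe, thr and trpn (3.68 to 4.20 per array). Its fold is then a bound against that level. Tables were read and drawn with Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

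With 3 arrays per group the number of arrays limits the precision. Simulated data with known changes were tested with the same steps: 67% of probe sets changed 2-fold and 96% of those changed 4-fold were called in CLA vs LA, with 7 unchanged probe sets called, and 69%, 96% and 7 in phenformin vs CLA. In phenformin vs LA, where nothing was changed, 0 were called. Of the simulated lists, 3 of 3 shifted and 0 of 22 unshifted ones were called. The simulated genes varied independently, so this does not test the list calls where genes vary together. An adjusted p under 0.05 was given to 7445, 7405 and 2038 of 45101 probe sets in the authors' deposited tables, and the same fit with controls included called all of them. The largest difference in a log2 fold change was 4.6e-08.

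The alternatives were the replicate number as a block, each array left out, a fit of the 2 groups compared, median centring, quantile normalization of the deposited values, a filter to 23938 probe sets whose highest group mean exceeds the median of all values (5.07), an intensity trend with robust estimation, array weights, a 2-fold minimum, and the mean of all probe sets of a gene. Added after the data were seen were the 3' minus 5' difference of pyruvate carboxylase as a covariate, different LA arrays behind the comparisons with LA, the mean of probe sets for the shared genes, and each array left out for the genes called in opposite directions. Dates and batches of hybridization were not used here.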

Results

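Gene expression was measured in 3T3-L1 adipocytes, a mouse preadipocyte line that is differentiated into fat cells in culture. The cells had received linoleic acid (LA), conjugated linoleic acid (CLA) or phenformin, and LA was the control, per the labels. LA and CLA are isomers: they share chain length and number of double bonds, which are conjugated in CLA and separated by a methylene group in LA. Phenformin is a biguanide that inhibits mitochondrial respiration and activates AMP-activated protein kinase (AMPK). The series addressed AMPK and prostaglandins in the response of adipocytes to CLA. Each of the 3 groups held 3 arrays, which the labels call biological replicates, so 9 arrays were compared. Doses, times, the CLA isomer and whether the phenformin dishes also held LA are not given in the labels used here. The treatments are therefore not known to be matched in dose or time. Values are log2 expression values of probe sets, and a gene is represented by its brightest probe set. Group levels are mean ± SD, amounts by which a gene rose or changed are log2 fold changes ± SE, and n = 3 arrays per group throughout.

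Correlations between arrays over probe sets ranged from 0.986 to 0.996 within groups and from 0.963 to 0.991 between groups, and the principal component that explained most variance carried 49.1% of it. Several control probe sets differed between LA and the treated arrays. The difference between the 3' and 5' probe sets of beta-actin, which grows as RNA or target is shortened, was 1.28 ± 0.39 in LA, 0.53 ± 0.10 in CLA and 0.56 ± 0.09 in phenformin. For pyruvate carboxylase this difference was 5.36 ± 0.43, 4.02 ± 0.63 and 3.95 ± 0.60 in the same order. The mean level of the bacterial and phage hybridization controls was 9.93 ± 0.21 in LA, 11.94 ± 0.82 in CLA and 10.95 ± 0.50 in phenformin. LA replicate 3 had the narrowest range, with a 99th percentile of 11.63 against 12.20 to 12.48 on the other arrays.

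**Figure D1:**
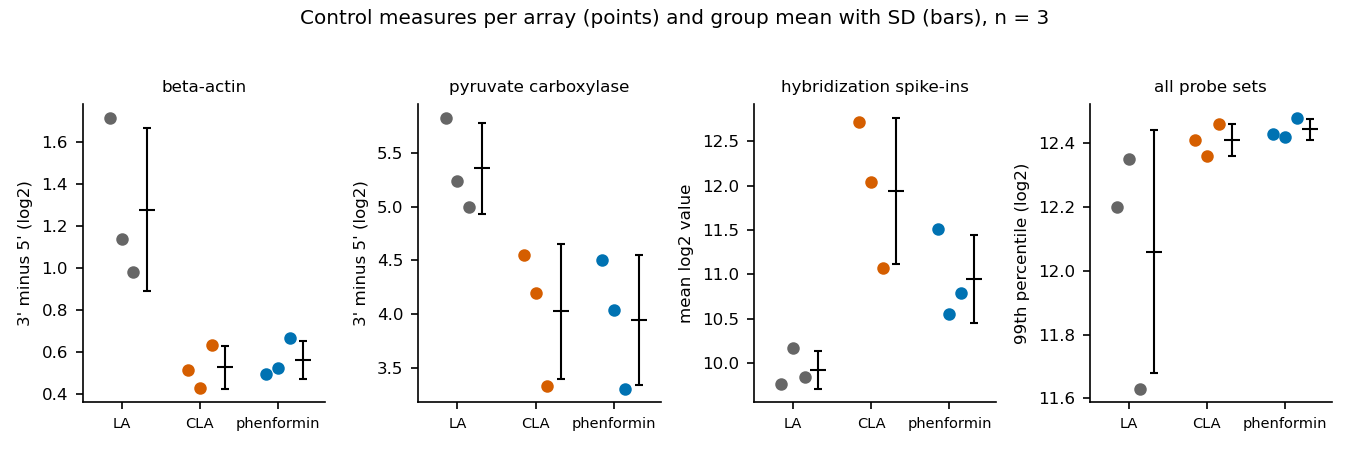
Values of the control probe sets on the 9 arrays, on the log2 scale, with each point an array and groups LA, CLA and phenformin side by side. LA arrays lie above the treated arrays in the beta-actin 3' minus 5' difference (means 1.28, 0.53 and 0.56) and below them in the level of the hybridization controls (means 9.93, 11.94 and 10.95).

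The comparison of CLA with LA asked which genes differ between adipocytes given a conjugated fatty acid and adipocytes given its non-conjugated isomer. Among the largest rises were those of Saa3 and Ptgs2. Saa3, an acute-phase serum amyloid gene, rose from 5.80 ± 0.60 in LA to 12.80 ± 0.03 in CLA, a 128-fold difference (limma adjusted p = 1.35e-07). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 3.05 ± 0.19, a value not above background, to 9.98 ± 0.24, or at least 64.5-fold (adjusted p = 8.32e-08). That bound holds for the brighter of its 2 probe sets only, since the other was not at or under background on every LA array. Pnpla3, a lipid droplet protein, fell with a log2 fold change of -3.68 ± 0.16, and Pparg, the nuclear receptor that directs adipocyte differentiation, with -1.25 ± 0.19 (adjusted p = 4.91e-07 to 0.00122).

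Among NF-kB targets and inflammatory cytokines, of the 25 measured members, 21 rose (21 rose and 1 fell when adjusted over the list alone), with a median log2 fold change 2.12, camera adjusted p = 3.38e-16. The chemokines Ccl2 and Ccl7 had log2 fold changes of 4.46 ± 0.10 and 3.64 ± 0.16, and the growth factor of macrophages Csf1 had 2.59 ± 0.11. Cxcl5, a neutrophil chemokine, rose by 6.25 ± 0.37, and the cytokine Il6 by 2.38 ± 0.31 (adjusted p = 3.65e-06 to 0.00055). Il6 lay near background in LA, at 3.32, 3.24 and 4.29 against levels of 3.80, 3.90 and 4.20, so the size of its rise is uncertain. Among the immediate early genes, which respond to stimuli within minutes, of the 12 measured members, 10 rose (10 rose when adjusted over the list alone), with a median log2 fold change 2.54, camera adjusted p = 2.04e-11. Ier3, Junb, Jun and Egr1 rose by 4.47 ± 0.29, 3.48 ± 0.16, 3.31 ± 0.16 and 3.27 ± 0.17. The epidermal growth factor family ligand Ereg and the AP-1 subunit Fosl1 rose by 5.74 ± 0.22 and 5.23 ± 0.15. In the list of preadipocyte, fibroblast and matrix genes, of the 18 measured members, 15 rose (15 rose when adjusted over the list alone), with a median log2 fold change 1.44, camera adjusted p = 1.91e-11. Postn and Thbs1, which encode matrix proteins, rose by 3.21 ± 0.14 and 2.83 ± 0.15, and the collagenase Mmp13 by 5.39 ± 0.18. These 3 lists were the ones still called with an estimated correlation, at adjusted p = 0.00558, 0.013 and 0.013. In the prostaglandin pathway, of the 18 measured members, 6 rose (6 rose and 1 fell when adjusted over the list alone). Prostaglandin pathway genes had a median log2 fold change 0.28, camera adjusted p = 0.0314, and adjusted p = 0.188 with an estimated correlation. Beside Ptgs2, the phospholipase Pla2g4a, the prostacyclin receptor Ptgir and the prostaglandin E synthase Ptges rose by 2.54 ± 0.21, 2.42 ± 0.20 and 1.73 ± 0.15. The call for the prostaglandin list was lost without LA replicate 2 (adjusted p = 0.0694) and with the 3' minus 5' covariate (0.111). The level of the hybridization controls also differed between the groups, from 9.93 ± 0.21 in LA to 11.94 ± 0.82 in CLA. That difference goes with every list of this comparison alike, and no control was tested against a list.

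In the integrated stress response, of the 24 measured members, 17 rose (20 rose when adjusted over the list alone). Integrated stress response genes had a median log2 fold change 1.12, camera adjusted p = 1.13e-12, and adjusted p = 0.117 with an estimated correlation. The transcription factors Atf3 and Ddit3 rose by 4.45 ± 0.15 and 1.70 ± 0.12, and the cystine transporter Slc7a11 by 3.51 ± 0.20. For the NRF2 oxidative stress targets, of the 14 measured members, 10 rose (11 rose when adjusted over the list alone). NRF2 target genes had a median log2 fold change 1.40, camera adjusted p = 2.28e-08, and adjusted p = 0.149 with an estimated correlation. The heme oxygenase Hmox1 rose by 3.76 ± 0.16 and the sulfiredoxin Srxn1 by 3.22 ± 0.27. Heat shock genes were led by Hspb1, a small heat shock protein, at 3.04 ± 0.18, and of the 10 measured members, 6 rose (8 rose when adjusted over the list alone). Heat shock genes had a median log2 fold change 0.997, camera adjusted p = 6.51e-05, and adjusted p = 0.304 with an estimated correlation. Among the endoplasmic reticulum chaperones, of the 20 measured members, 9 rose (15 rose when adjusted over the list alone). Chaperone genes had a median log2 fold change 0.64, camera adjusted p = 1.75e-05, and adjusted p = 0.201 with an estimated correlation. The chaperone Hspa5 rose by 1.45 ± 0.20. Among the aminoacyl-tRNA synthetases, which charge transfer RNAs, of the 12 measured members, 11 rose (11 rose when adjusted over the list alone). Synthetase genes had a median log2 fold change 0.87, camera adjusted p = 5.98e-07, and adjusted p = 0.262 with an estimated correlation. Cholesterol synthesis genes included Lss and Mvd, enzymes of the sterol pathway, at 1.33 ± 0.11 and 1.26 ± 0.11, and of the 18 measured members, 12 rose (13 rose when adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change 0.99, camera adjusted p = 7.61e-07, and adjusted p = 0.201 with an estimated correlation. The beta-actin 3' minus 5' difference, which goes with every list of this comparison alike, went from 1.28 ± 0.39 in LA to 0.53 ± 0.10 in CLA.

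In fatty acid and triglyceride synthesis, of the 22 measured members, 4 rose and 10 fell (4 rose and 10 fell when adjusted over the list alone). Fat synthesis genes had a median log2 fold change -0.32, camera adjusted p = 0.00286, and adjusted p = 0.424 with an estimated correlation. Gpam, the acyltransferase that starts glycerolipid synthesis, and Thrsp, a regulator of lipogenesis, changed by -2.44 ± 0.19 and -1.62 ± 0.12, while the elongase Elovl6 rose by 2.03 ± 0.15. Fasn, the fatty acid synthase, had -0.79 ± 0.20 (adjusted p = 0.0203), a call lost without LA replicate 1 (adjusted p = 0.0677), without LA replicate 2 (0.0721), without CLA replicate 2 (0.0848) and with the 3' minus 5' covariate (-0.57 ± 0.30, 0.27). Among genes of adipocyte identity, of the 17 measured members, 1 rose and 5 fell (2 rose and 6 fell when adjusted over the list alone). Adipocyte identity genes had a median log2 fold change -0.14, camera adjusted p = 0.0257, and adjusted p = 0.477 with an estimated correlation. The transcription factor Klf15 changed by -2.02 ± 0.13 and Pck1, an enzyme of glyceroneogenesis, by -3.05 ± 0.34. Pck1 varied within LA, at 8.29, 8.14 and 6.67 in replicates 1, 2 and 3. The adipocyte identity call was lost without LA replicate 2 (adjusted p = 0.0979). In insulin signalling, of the 13 measured members, 7 fell (1 rose and 7 fell when adjusted over the list alone). Insulin signalling genes had a median log2 fold change -0.63, camera adjusted p = 0.000269, and adjusted p = 0.201 with an estimated correlation. The transcription factor Foxo1 and Tbc1d4, a regulator of glucose transporter traffic, changed by -1.82 ± 0.14 and -1.64 ± 0.19. The probe sets of the insulin receptor Insr disagreed: the brightest had -1.28 ± 0.18, another was called in the opposite direction, and their mean was -0.12. In lipolysis, of the 10 measured members, 3 fell (3 fell when adjusted over the list alone). Lipolysis genes had a median log2 fold change -0.22, camera adjusted p = 0.033, and adjusted p = 0.389 with an estimated correlation. The lipases Ces1d and Mgll changed by -2.36 ± 0.26 and -1.15 ± 0.14. The lipolysis call was lost without LA replicate 1 (adjusted p = 0.0605), without LA replicate 2 (0.0853), without CLA replicate 2 (0.0811) and with the 3' minus 5' covariate (0.107). Beside these lists, the preadipocyte, fibroblast and matrix list was higher by a median of 1.44. The pyruvate carboxylase 3' minus 5' difference, which goes with every list of this comparison alike, fell from 5.36 ± 0.43 to 4.02 ± 0.63.

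For brown and beige adipocyte genes, of the 10 measured members, 4 fell (4 fell when adjusted over the list alone), and the median (0.04), the mean (-0.76) and the direction of the test (lower, camera adjusted p = 0.0408) differed in sign. The lipid droplet protein Cidea and the respiratory chain subunits Cox7a1 and Cox8b changed by -3.46 ± 0.51, -2.51 ± 0.19 and -2.23 ± 0.20. The list had adjusted p = 0.201 with an estimated correlation, and its call was lost without LA replicate 1 (adjusted p = 0.0506), without CLA replicate 3 (0.0745), after median centring (0.0571), after quantile normalization (0.172), over means of probe sets (0.0707) and with the 3' minus 5' covariate (0.107). Its median was -0.05 after quantile normalization and -1.10 without dim probe sets, and Cidea lost its call with the 3' minus 5' covariate (-2.56 ± 0.74, adjusted p = 0.0558). Fatty acid oxidation, oxidative phosphorylation, glycolysis and the AMPK complex and its regulators were not called as lists. In fatty acid oxidation, of the 18 measured members, 3 rose and 2 fell (3 rose and 2 fell when adjusted over the list alone), among them Cpt1a, the mitochondrial carnitine acyltransferase, at 0.88 ± 0.12 (median 0.10, -0.24 after quantile normalization, test direction lower, camera adjusted p = 0.964). In oxidative phosphorylation, of the 23 measured members, 2 rose and 1 fell (2 rose and 1 fell when adjusted over the list alone) (median 0.14, adjusted p = 0.505), and quantile normalization gave a median of -0.19 (adjusted p = 0.0214). In glycolysis, of the 13 measured members, 4 rose (4 rose when adjusted over the list alone), led by the glucose transporter Slc2a1 at 2.27 ± 0.32 (median 0.24, adjusted p = 0.0869), a list called higher without LA replicate 2 (median 0.44, adjusted p = 0.0124). In the AMPK list, of the 12 measured members, 1 rose and 3 fell (2 rose and 4 fell when adjusted over the list alone), with the regulatory subunits Prkab2 at 1.38 ± 0.15 and Prkag2 at -1.30 ± 0.21 (median -0.29, 0.05 over means of probe sets, adjusted p = 0.167). That list was called lower without CLA replicate 3 (adjusted p = 0.0434) and with the 3' minus 5' covariate (median -0.47, 0.0429).

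Among cell cycle genes, of the 18 measured members, 8 rose and 1 fell (13 rose and 1 fell when adjusted over the list alone). Cell cycle genes had a median log2 fold change 0.71, camera adjusted p = 0.000633, and adjusted p = 0.442 with an estimated correlation. The cyclin Ccna2 rose by 1.68 ± 0.25, and the list's call was lost with the 3' minus 5' covariate (adjusted p = 0.276). Markers of other cell types were not called: for macrophages, of the 12 measured members, 1 rose (3 rose and 1 fell when adjusted over the list alone) (median 0.09, adjusted p = 0.817). For endothelium, of the 10 measured members, 1 rose (0 passed when adjusted over the list alone) (median 0.10, adjusted p = 0.794), and for muscle, of the 10 measured members, 0 passed (0 passed when adjusted over the list alone) (median -0.09, adjusted p = 0.222). The endothelial markers Tek and Vwf and the muscle marker Myf5 were not above background in any group, so their lack of a call says little. Among hypoxia genes, of the 12 measured members, 4 rose and 2 fell (5 rose and 2 fell when adjusted over the list alone), and the median was -0.06, the mean 0.17 and the test direction higher (adjusted p = 0.598). The median was 0.09 without dim probe sets, and the list was called by fry (adjusted p = 0.0173). Among p53 targets and apoptosis genes, of the 11 measured members, 5 rose and 1 fell (5 rose and 2 fell when adjusted over the list alone), with the growth arrest gene Gadd45a at 2.84 ± 0.12 and the cell cycle inhibitor Cdkn1a at 2.02 ± 0.19 (median 0.11, -0.04 after quantile normalization, adjusted p = 0.132). That list was called over means of probe sets (median 0.24, adjusted p = 0.0457) and by fry (0.000238).

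The adiponectin gene Adipoq and the desaturase gene Scd1 lay near the highest values of their arrays (13.57 to 14.78), where the scale leaves little room for a difference. Adipoq was at 14.00 ± 0.43 in LA and 14.07 ± 0.07 in CLA, and Scd1 at 14.01 ± 0.50 and 14.31 ± 0.01 (adjusted p = 0.832 and 0.37). Quantile normalization turned the difference in Adipoq to -0.31 (adjusted p = 0.0357) and that in Scd1 to -0.09. The leptin gene Lep lay at 4.07 ± 0.51 in LA and, not above background, at 3.66 ± 0.13 in CLA (adjusted p = 0.237). For the AMPK catalytic subunits Prkaa1 and Prkaa2 the differences of CLA from LA did not pass the threshold, with 95% intervals of -1.66 to 0.56 and -0.10 to 0.43. The largest falls included Cryl1 at -4.82 ± 0.63, E2f5 at -4.25 ± 0.59 and Nrip2 at -3.10 ± 0.64, whose further probe sets were not called lower. Itih4, Ccl6, Depp1 and Strip2 fell too, with log2 fold changes of -4.005 ± 0.20, -3.66 ± 0.33, -3.89 ± 0.60 and -3.43 ± 0.28. Depp1 was highest in replicate 3 of every group, at 11.01 in LA and 8.16 in CLA.

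In all, 7426 of 45037 probe sets were called between CLA and LA (16.5%; limma, adjusted p under 0.05), 4559 higher and 2867 lower. Of 18193 genes 3675 were called, 2296 higher and 1379 lower, and 1227 of them differed at least 2-fold. Of the called probe sets 61.4% were higher, against 46.6% after quantile normalization of the deposited values. Of the 25 lists 16 were called, 11 higher and 5 lower, and 3 with an estimated correlation. Leaving out CLA replicate 1 gave 4788 probe sets, 1641 of them lower, and the lower count was 1823 without LA replicate 1 and 1787 without CLA replicate 2. With the pyruvate carboxylase 3' minus 5' difference as a covariate, an alternative added after the data were seen, 4895 probe sets were called.

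**Figure D2:**
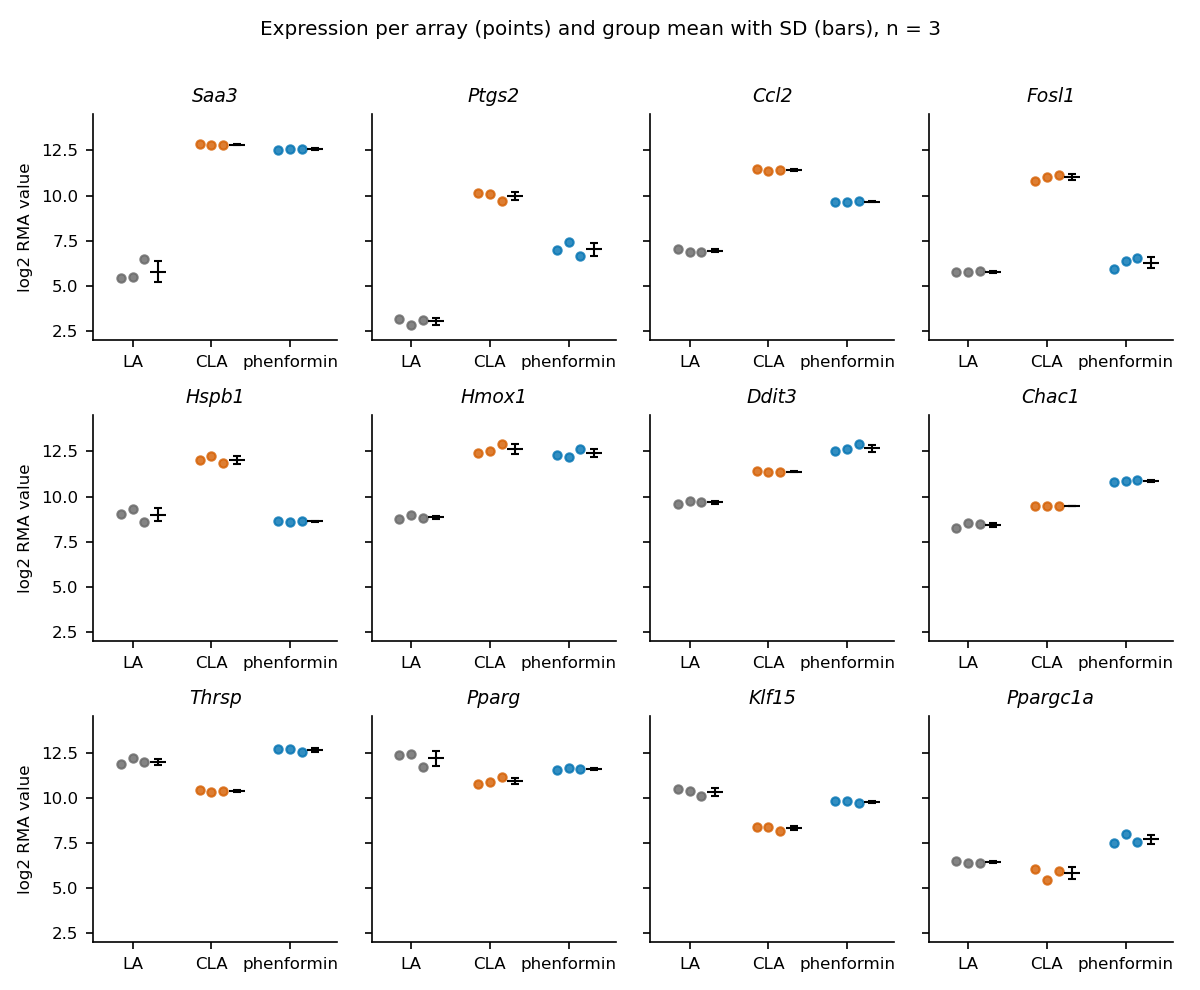
Log2 expression values of named genes on each of the 9 arrays, with each point an array and the bars the mean ± SD of the LA, CLA and phenformin groups (n = 3). Ptgs2 lay at 9.98 in CLA and 3.05 in LA.

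The comparison of phenformin with LA asked what a compound that activates AMPK does to adipocyte gene expression. Saa3 and Ptgs2 were among the largest rises here too. Saa3 reached 12.57 ± 0.04 against 5.80 ± 0.60 in LA, or 109-fold (limma adjusted p = 6.87e-07), and Ptgs2 reached 7.03 ± 0.37 against 3.05 ± 0.19, which is not above background, or at least 8.38-fold (adjusted p = 2.54e-06). For Ptgs2 the bound again holds for the brighter of its 2 probe sets only. Genes of the integrated stress response, the arm of stress signalling that acts through translation, formed the list with the smallest p by camera at the preset correlation (8.37e-19). With an estimated correlation they were not called (adjusted p = 0.0546), and there and by fry NF-kB targets and cytokines had the smallest p (adjusted p = 0.0101 and 1.18e-06). Ddit3, a transcription factor of that response, rose by 2.999 ± 0.12 (adjusted p = 1.61e-06). Pck1, an enzyme of glyceroneogenesis, and Itih4, a secreted protease inhibitor family member, fell, with log2 fold changes of -2.82 ± 0.34 and -3.52 ± 0.20.

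In the integrated stress response, of the 24 measured members, 20 rose (21 rose when adjusted over the list alone). Integrated stress response genes had a median log2 fold change 1.95, camera adjusted p = 8.37e-19, and adjusted p = 0.0546 with an estimated correlation. The glutathione-degrading enzyme Chac1, the pseudokinase Trib3 and the phosphatase subunit Ppp1r15a rose by 2.44 ± 0.10, 2.27 ± 0.23 and 3.28 ± 0.15. Among the aminoacyl-tRNA synthetases, of the 12 measured members, 11 rose (11 rose when adjusted over the list alone). Synthetase genes had a median log2 fold change 1.06, camera adjusted p = 1.34e-08, and adjusted p = 0.201 with an estimated correlation. Aars and Cars, the alanine and cysteine enzymes, rose by 1.60 ± 0.17 and 1.53 ± 0.11. For cholesterol synthesis, of the 18 measured members, 14 rose (17 rose when adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change 1.14, camera adjusted p = 9.94e-12, and adjusted p = 0.117 with an estimated correlation. Lss, Mvd and Fdps rose by 1.81 ± 0.11, 1.60 ± 0.11 and 1.22 ± 0.13, and the brightest probe set of Sc5d by 1.98 ± 0.15, while another of its probe sets was called lower and their mean was not called (adjusted p = 0.134). Among the endoplasmic reticulum chaperones, of the 20 measured members, 6 rose (9 rose when adjusted over the list alone). Chaperone genes had a median log2 fold change 0.41, camera adjusted p = 0.014, and adjusted p = 0.407 with an estimated correlation. Edem1, a factor of protein disposal, rose by 1.74 ± 0.15, and the list's call was lost after quantile normalization (adjusted p = 0.244) and without dim probe sets (0.132). For NRF2 targets, of the 14 measured members, 6 rose and 1 fell (8 rose and 1 fell when adjusted over the list alone). NRF2 target genes had a median log2 fold change 0.39, camera adjusted p = 0.00124, and adjusted p = 0.304 with an estimated correlation, and Hmox1 rose by 3.53 ± 0.16. Heat shock genes were not called as a list: of the 10 measured members, 1 rose and 1 fell (1 rose and 1 fell when adjusted over the list alone) (median -0.15, adjusted p = 0.542), but were called lower without LA replicate 3 (median -0.32, adjusted p = 0.0478). For these lists, as for every list of this comparison, the beta-actin 3' minus 5' difference was 0.56 ± 0.09 in phenformin against 1.28 ± 0.39 in LA.

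Among NF-kB targets and inflammatory cytokines, of the 25 measured members, 16 rose (16 rose and 1 fell when adjusted over the list alone), with a median log2 fold change 1.498, camera adjusted p = 9.32e-11, and in the preadipocyte, fibroblast and matrix list, of the 18 measured members, 12 rose (14 rose when adjusted over the list alone), with a median log2 fold change 0.87, camera adjusted p = 1.92e-09. These lists were the ones still called with an estimated correlation, at adjusted p = 0.0101 and 0.0167. Ccl2, Il6 and Cxcl5 rose by 2.71 ± 0.10, 2.36 ± 0.31 and 5.88 ± 0.37, with Il6 near background in LA, and the matrix genes Postn and Col1a2 by 3.29 ± 0.14 and 1.53 ± 0.17. The matrix proteases Mmp13 and Mmp3 rose by 4.30 ± 0.18 and 3.92 ± 0.25, and the interferon-induced gene Ifit1 by 3.54 ± 0.27. Among the immediate early genes, of the 12 measured members, 6 rose (6 rose when adjusted over the list alone). Immediate early genes had a median log2 fold change 0.54, camera adjusted p = 0.0025, and adjusted p = 0.149 with an estimated correlation, and Fos rose by 2.45 ± 0.29. In the prostaglandin pathway, of the 18 measured members, 5 rose and 1 fell (5 rose and 1 fell when adjusted over the list alone), and the median was -0.0048 and the mean 0.59 (adjusted p = 0.133). Its median was 0.03 after quantile normalization and 0.28 without dim probe sets, and it was called higher by fry (adjusted p = 7.96e-05). Pla2g4a, Ptgir and Ptges rose by 2.97 ± 0.21, 1.91 ± 0.20 and 1.29 ± 0.15. Among p53 targets and apoptosis genes, of the 11 measured members, 6 rose (7 rose when adjusted over the list alone). Genes of the p53 list had a median log2 fold change 0.78, camera adjusted p = 0.00112, and adjusted p = 0.128 with an estimated correlation. Gadd45a led them at 3.84 ± 0.12. Among cell cycle genes, of the 18 measured members, 9 rose (12 rose and 1 fell when adjusted over the list alone). Cell cycle genes had a median log2 fold change 0.70, camera adjusted p = 0.000419, and adjusted p = 0.435 with an estimated correlation. The cell cycle call was lost with the 3' minus 5' covariate (adjusted p = 0.276). The hybridization controls, whose difference goes with every list of this comparison alike, went from 9.93 ± 0.21 in LA to 10.95 ± 0.50 in phenformin.

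For adipocyte identity, of the 17 measured members, 3 rose and 3 fell (3 rose and 4 fell when adjusted over the list alone), and the median (0.10, -0.22 after quantile normalization) and mean (-0.09) differed in sign (test direction lower, adjusted p = 0.554). The glucose transporter Slc2a4 rose by 1.06 ± 0.19, and the lipid droplet gene Plin4 changed by -1.004 ± 0.17, calls lost with the 3' minus 5' covariate, which widened the SE (1.003 ± 0.32 and -0.89 ± 0.28, adjusted p = 0.0872 and 0.0905). Pparg had -0.58 ± 0.19 (adjusted p = 0.0619), and was called without LA replicate 3 (-0.81, adjusted p = 0.00261), after quantile normalization (-0.95, 0.000296), without dim probe sets (0.0457), with array weights (0.00163) and over means of probe sets (0.0426). In fatty acid and triglyceride synthesis, of the 22 measured members, 7 rose and 5 fell (8 rose and 5 fell when adjusted over the list alone) (median 0.37, -0.01 after quantile normalization, adjusted p = 0.243). Elovl6, the malic enzyme Me1 and the acetyl-CoA synthetase Acss2 rose by 1.72 ± 0.15, 1.64 ± 0.14 and 1.49 ± 0.11, and Pnpla3 changed by -1.90 ± 0.16. In insulin signalling, of the 13 measured members, 6 fell (1 rose and 6 fell when adjusted over the list alone). Insulin signalling genes had a median log2 fold change -0.29, camera adjusted p = 0.00236, and adjusted p = 0.278 with an estimated correlation, a call lost over means of probe sets (adjusted p = 0.0707). Foxo1 changed by -1.29 ± 0.14. The brightest probe set of Insr had -0.98 ± 0.18, another was called in the opposite direction, and their mean was 0.02, and the call was lost with the 3' minus 5' covariate (-0.69 ± 0.28, adjusted p = 0.173). In lipolysis, of the 10 measured members, 1 fell (1 fell when adjusted over the list alone) (median -0.02, adjusted p = 0.542), and Ces1d changed by -1.84 ± 0.26. The preadipocyte, fibroblast and matrix list moved beside these, by a median of 0.87. The pyruvate carboxylase 3' minus 5' difference, which goes with every list of this comparison alike, was 3.95 ± 0.60 against 5.36 ± 0.43.

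Oxidative phosphorylation genes, which encode the respiratory chain that phenformin inhibits, were called higher: of the 23 measured members, 4 rose (9 rose and 1 fell when adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change 0.31, camera adjusted p = 0.0017, and adjusted p = 0.553 with an estimated correlation. That call was lost without LA replicate 3 (adjusted p = 0.0536), after quantile normalization (0.905) and by fry (0.0685), and quantile normalization gave a median of -0.05 (adjusted p = 0.905). For brown and beige adipocyte genes, of the 10 measured members, 3 fell (3 fell when adjusted over the list alone). Brown and beige genes had a median log2 fold change -0.03, camera adjusted p = 0.0497, and adjusted p = 0.201 with an estimated correlation. Cox7a1 and Cox8b changed by -1.27 ± 0.19 and -1.14 ± 0.20, and Cidea by -3.17 ± 0.51, a call lost with the 3' minus 5' covariate (-2.21 ± 0.77, adjusted p = 0.116). The list's call was lost without LA replicate 1 (adjusted p = 0.0676), without CLA replicate 1 (0.0582), without CLA replicate 2 (0.0599), without CLA replicate 3 (0.0552), without phenformin replicate 2 (0.0625), without phenformin replicate 3 (0.0501), in a fit of the groups compared alone (0.0657), after median centring (0.0561), after quantile normalization (0.237), with array weights (0.0501), over means of probe sets (0.0782) and with the 3' minus 5' covariate (0.137), and its median turned to 0.17 with the covariate. The AMPK list was not called: of the 12 measured members, 2 rose and 2 fell (3 rose and 4 fell when adjusted over the list alone) (median 0.15, -0.06 after quantile normalization, adjusted p = 0.896). The catalytic subunit Prkaa2 rose by 0.91 ± 0.12 and the coactivator of mitochondrial biogenesis Ppargc1a by 1.26 ± 0.18. In fatty acid oxidation, of the 18 measured members, 1 rose and 2 fell (3 rose and 3 fell when adjusted over the list alone) (median 0.21, -0.10 after quantile normalization, adjusted p = 0.628), and in glycolysis, of the 13 measured members, 4 rose and 1 fell (4 rose and 1 fell when adjusted over the list alone) (median 0.38, adjusted p = 0.0535). The glycolysis list was called higher without LA replicate 1 (adjusted p = 0.045), without LA replicate 2 (median 0.64, 0.00732) and without phenformin replicate 2 (0.0276). Among macrophage markers, of the 12 measured members, 2 passed the test, with lower values (2 when adjusted over the list alone) (median -0.03, adjusted p = 0.275). Cd14 fell, at -0.73 ± 0.20, whereas Adgre1 lay at 3.80 ± 0.08 in LA, near background, and at 3.40 ± 0.11 with phenformin, not above it, so no fall is shown for it. The call for Adgre1 was lost without LA replicate 1 (adjusted p = 0.123), without LA replicate 2 (0.134), without CLA replicate 1 (0.0647), without CLA replicate 3 (0.0539), without phenformin replicate 1 (0.115), without phenformin replicate 2 (0.18), without phenformin replicate 3 (0.0656), in a fit of the groups compared alone (0.0508), after quantile normalization (0.058) and with the 3' minus 5' covariate (-0.38 ± 0.20, 0.307). The call for Cd14 was lost without LA replicate 1 (adjusted p = 0.0634), without LA replicate 3 (0.0892), without CLA replicate 1 (0.0566), without phenformin replicate 1 (0.119), without phenformin replicate 3 (0.0942) and with the 3' minus 5' covariate (-0.63 ± 0.34, 0.31). Among endothelial markers, of the 10 measured members, 0 passed (0 passed when adjusted over the list alone) (median -0.05, mean 0.02, 0.24 without dim probe sets, adjusted p = 0.676). Among muscle markers, of the 10 measured members, 0 passed (0 passed when adjusted over the list alone) (median -0.14, adjusted p = 0.113). The markers Aif1, Pecam1, Tek, Vwf and Myf5 were not above background in LA or phenformin, so their lack of a call says little. For hypoxia, of the 12 measured members, 2 rose (2 rose when adjusted over the list alone), with a median of -0.08, a mean of 0.09 and a test direction of higher (adjusted p = 0.852), and 0.15 without dim probe sets.

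In all, 7401 probe sets were called between phenformin and LA (16.4%), 5168 higher and 2233 lower, and 3422 genes, 2493 higher and 929 lower, of which 1074 differed at least 2-fold. Of the called probe sets 69.8% were higher, against 48.8% after quantile normalization. The median of all log2 fold changes was -0.0038, and 0.11 without dim probe sets. Of the 25 lists 13 were called, 11 higher and 2 lower, and 2 with an estimated correlation. The largest falls were those of Cryl1 at -4.63 ± 0.63, E2f5 at -4.37 ± 0.59 and Depp1 at -4.13 ± 0.60, and the further probe sets of Cryl1, E2f5, Nrip2 and Aif1l were not called lower. Depp1, like these genes, was highest in replicate 3 of every group, at 11.01 in LA and 7.99 in phenformin. With the 3' minus 5' covariate Depp1 had -5.96 ± 0.67. Itih4 fell with a log2 fold change of -3.52 ± 0.20, and Vstm2a, with a single probe set, from 6.10 ± 0.28 to 2.97 ± 0.07, which is not above background, or at least 4.79-fold. Without LA replicate 1, phenformin replicate 1 or phenformin replicate 2, the count of probe sets called lower was 1389, 1243 and 1301. With the 3' minus 5' difference as a covariate 3647 probe sets were called.

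**Figure D3:**
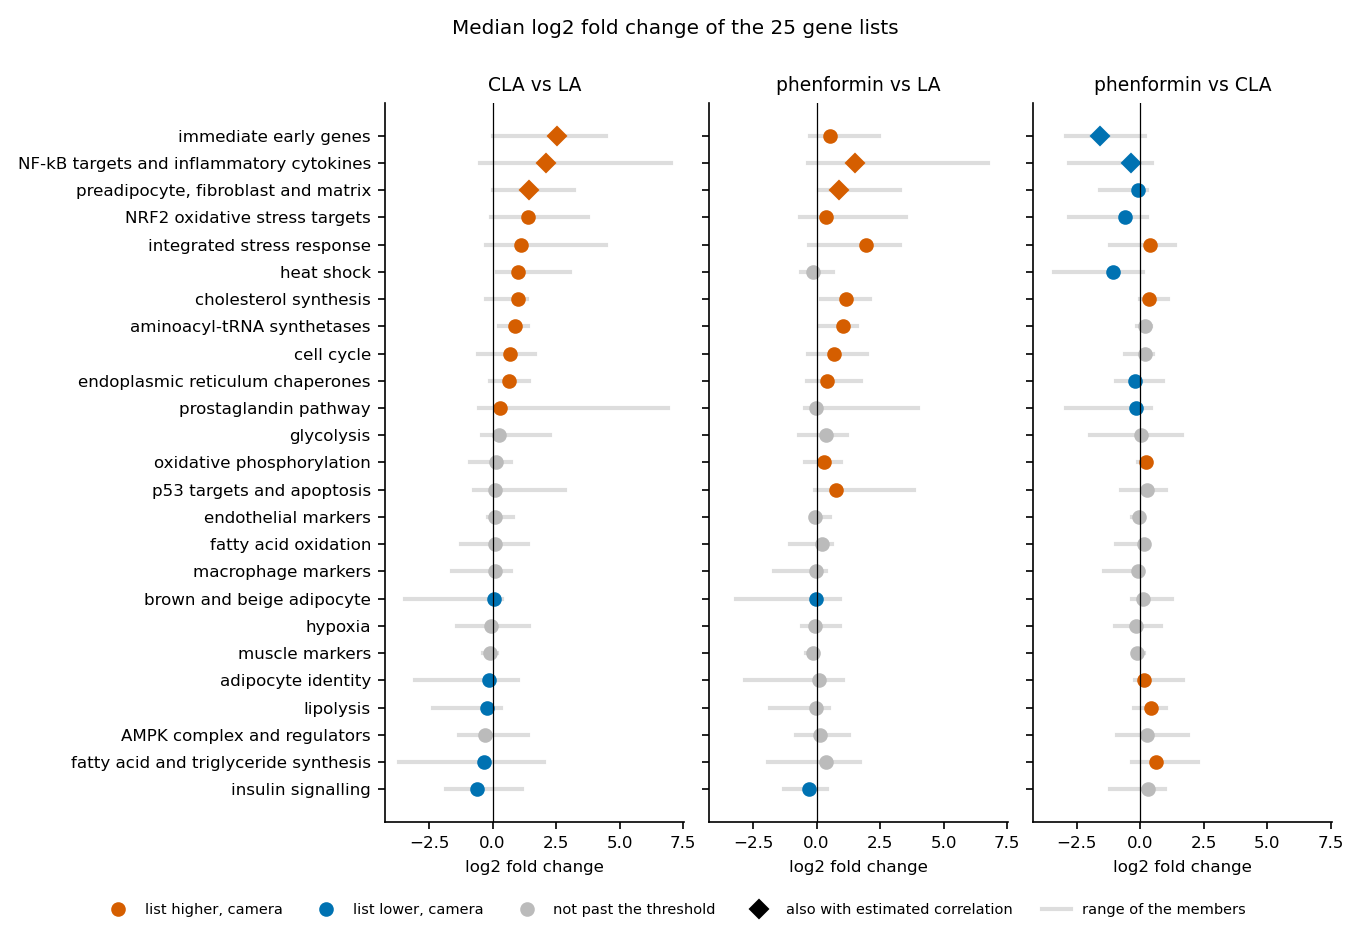
Median log2 fold change of each of the 25 gene lists in the 3 comparisons, with points for lists called and not called by camera. Immediate early genes had medians of 2.54, 0.54 and -1.60 in CLA vs LA, phenformin vs LA and phenformin vs CLA.

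The comparison of phenformin with CLA asked where the treatments differ from each other. Ereg had a log2 fold change of -5.17 ± 0.22 and Fosl1 one of -4.73 ± 0.15 (limma adjusted p = 7.69e-07 to 2.5e-06). Ptgs2 was lower with phenformin, at 7.03 ± 0.37 against 9.98 ± 0.24 with CLA (adjusted p = 4.95e-05). Thrsp was 4.82-fold higher, at 12.64 ± 0.11 against 10.38 ± 0.07 (adjusted p = 1.22e-05).

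Among the immediate early genes, of the 12 measured members, 9 fell (9 fell when adjusted over the list alone), with a median log2 fold change -1.60, camera adjusted p = 1.43e-13, and among NF-kB targets and inflammatory cytokines, of the 25 measured members, 8 fell (1 rose and 10 fell when adjusted over the list alone), with a median log2 fold change -0.37, camera adjusted p = 1.29e-06. These lists were the ones called with an estimated correlation, at adjusted p = 0.0101 and 0.0156. Egr1, Jun and Myc changed by -2.94 ± 0.17, -1.99 ± 0.16 and -1.45 ± 0.12, and the chemokine Ccl2 by -1.75 ± 0.10. The chemokine Cxcl2 was at least 5.6-fold lower with phenformin, where it lay at 3.52 ± 0.10, not above background, against 6.32 ± 0.48. The difference in Il6 was -0.02 ± 0.31, with a 95% interval of -0.71 to 0.68. Among the heat shock genes, of the 10 measured members, 5 fell (7 fell when adjusted over the list alone). Heat shock genes had a median log2 fold change -1.07, camera adjusted p = 2.2e-07, and adjusted p = 0.201 with an estimated correlation. Hspb1 and Hsph1 changed by -3.39 ± 0.18 and -1.98 ± 0.24. Among NRF2 targets, of the 14 measured members, 7 fell (9 fell when adjusted over the list alone). NRF2 target genes had a median log2 fold change -0.63, camera adjusted p = 2.78e-07, and adjusted p = 0.174 with an estimated correlation. The sulfiredoxin Srxn1 led them at -2.82 ± 0.27. In the prostaglandin pathway, of the 18 measured members, 1 fell (1 fell when adjusted over the list alone), namely Ptgs2. Prostaglandin pathway genes had a median log2 fold change -0.17, camera adjusted p = 0.0458, and adjusted p = 0.201 with an estimated correlation. The prostaglandin call was lost without LA replicate 2 (adjusted p = 0.0514), without LA replicate 3 (0.0567), without CLA replicate 3 (0.112), without phenformin replicate 1 (0.113), in a fit of the groups compared alone (0.0504), with array weights (0.0598) and over means of probe sets (0.0536). In the preadipocyte, fibroblast and matrix list, of the 18 measured members, 3 fell (4 fell when adjusted over the list alone). Matrix genes had a median log2 fold change -0.11, camera adjusted p = 0.0189, and adjusted p = 0.201 with an estimated correlation, a call lost without phenformin replicate 2 (adjusted p = 0.0559) and over means of probe sets (0.0536).

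In fatty acid and triglyceride synthesis, of the 22 measured members, 11 rose (13 rose when adjusted over the list alone). Fat synthesis genes had a median log2 fold change 0.62, camera adjusted p = 4.19e-11, and adjusted p = 0.156 with an estimated correlation. Pnpla3 was higher by 1.78 ± 0.16, the carbohydrate-responsive factor Mlxipl by 1.36 ± 0.18 and Acaca, the acetyl-CoA carboxylase, by 0.98 ± 0.15. For adipocyte identity, of the 17 measured members, 2 rose (5 rose when adjusted over the list alone), namely Slc2a4 at 1.66 ± 0.19 and Klf15 at 1.47 ± 0.13. Adipocyte identity genes had a median log2 fold change 0.15, camera adjusted p = 0.0239, and adjusted p = 0.474 with an estimated correlation. That call was lost without CLA replicate 2 (adjusted p = 0.0511) and by fry (0.0685). In lipolysis, of the 10 measured members, 1 rose (2 rose when adjusted over the list alone), namely Mgll at 0.99 ± 0.14. Lipolysis genes had a median log2 fold change 0.40, camera adjusted p = 0.0257, and adjusted p = 0.372 with an estimated correlation. The lipolysis call was lost without CLA replicate 2 (adjusted p = 0.0771), without phenformin replicate 1 (0.0512), without dim probe sets (0.12), over means of probe sets (0.0707) and by fry (0.0732). In the integrated stress response, of the 24 measured members, 6 rose and 1 fell (13 rose and 2 fell when adjusted over the list alone). Integrated stress response genes had a median log2 fold change 0.38, camera adjusted p = 6.83e-06, and adjusted p = 0.218 with an estimated correlation. Chac1 and Ddit3 were higher by 1.36 ± 0.10 and 1.30 ± 0.12, and Atf3 was lower, at -1.19 ± 0.15. For cholesterol synthesis, of the 18 measured members, 2 rose (6 rose when adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change 0.34, camera adjusted p = 9.12e-05, and adjusted p = 0.264 with an estimated correlation. In oxidative phosphorylation, of the 23 measured members, 0 passed (0 passed when adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change 0.23, camera adjusted p = 0.000686, and adjusted p = 0.514 with an estimated correlation, a call lost by fry (adjusted p = 0.196). Among the endoplasmic reticulum chaperones, of the 20 measured members, 1 rose and 1 fell (2 rose and 2 fell when adjusted over the list alone), namely Herpud1 at 0.88 ± 0.14 and Creld2 at -0.95 ± 0.15. Chaperone genes had a median log2 fold change -0.23, camera adjusted p = 0.0314, and adjusted p = 0.442 with an estimated correlation. That call was lost without CLA replicate 1 (adjusted p = 0.0586), without CLA replicate 3 (0.118), without phenformin replicate 1 (0.0512), over means of probe sets (0.0509) and by fry (0.131). The level of the hybridization controls moved with this comparison too, at 10.95 ± 0.50 with phenformin and 11.94 ± 0.82 with CLA.

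The other lists were not called between phenformin and CLA. In the AMPK list, of the 12 measured members, 2 rose and 1 fell (3 rose and 1 fell when adjusted over the list alone), with Ppargc1a at 1.87 ± 0.18, Prkaa2 at 0.75 ± 0.12 and Prkab2 at -0.92 ± 0.15 (median 0.27, adjusted p = 0.116), called higher without CLA replicate 3 (median 0.43, adjusted p = 0.0209). In fatty acid oxidation, of the 18 measured members, 2 fell (2 fell when adjusted over the list alone), with Cpt1a at -0.72 ± 0.12, not called over means of probe sets (adjusted p = 0.161) (median 0.14, adjusted p = 0.598). In glycolysis, of the 13 measured members, 1 rose and 1 fell (1 rose and 2 fell when adjusted over the list alone), with Pfkfb3 at 1.64 ± 0.26 and Slc2a1 at -2.002 ± 0.32 (median 0.02, mean -0.05, adjusted p = 0.852). For brown and beige adipocyte genes, of the 10 measured members, 2 rose (2 rose when adjusted over the list alone) (median 0.09, adjusted p = 0.267), called by fry (adjusted p = 0.0073). For insulin signalling, of the 13 measured members, 1 rose (4 rose and 1 fell when adjusted over the list alone) (median 0.30, adjusted p = 0.0535), called higher without LA replicate 1 (adjusted p = 0.041), without LA replicate 3 (0.0389), without CLA replicate 1 (0.036), without phenformin replicate 3 (0.0225), in a fit of the groups compared alone (0.0339) and with the 3' minus 5' covariate (0.0472). Among p53 targets and apoptosis genes, of the 11 measured members, 3 rose (4 rose and 2 fell when adjusted over the list alone), with Gadd45a at 0.997 ± 0.12 (median 0.27, adjusted p = 0.0869), called by fry (adjusted p = 0.0184). Among aminoacyl-tRNA synthetases, of the 12 measured members, 0 passed (1 rose when adjusted over the list alone) (median 0.17, adjusted p = 0.084), called higher without LA replicate 3 (adjusted p = 0.0491) and in a fit of the groups compared alone (0.0464), and among cell cycle genes, of the 18 measured members, 1 fell (1 fell when adjusted over the list alone) (median 0.20, adjusted p = 0.905). For hypoxia, of the 12 measured members, 1 rose and 1 fell (2 rose and 5 fell when adjusted over the list alone) (median -0.17, adjusted p = 0.267). Among macrophage markers, of the 12 measured members, 1 fell (1 fell when adjusted over the list alone), namely Cd14 at -1.44 ± 0.20 (median -0.08, adjusted p = 0.113), a list called by fry (adjusted p = 0.0458). Endothelial markers had a median of -0.06 (adjusted p = 0.303; of the 10 measured members, 0 passed (0 passed when adjusted over the list alone)) and muscle markers one of -0.12 and a mean of -0.05 (adjusted p = 0.752; of the 10 measured members, 0 passed (0 passed when adjusted over the list alone)), with 0.13 without dim probe sets.

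In all, 2048 probe sets were called between phenformin and CLA (4.55%), 1292 higher and 756 lower, and 1147 genes, 719 higher and 428 lower, of which 333 differed at least 2-fold. Of the called probe sets 63.1% were higher, against 52.4% after quantile normalization, and of the 25 lists 13 were called, 6 higher and 7 lower, and 2 with an estimated correlation. The count of probe sets rested on single arrays: it was 3085 without LA replicate 3, 900 and 961 without CLA replicates 1 and 2, and 1084, 820 and 1304 without phenformin replicates 1, 2 and 3. The gene count was 512, 550, 600, 463 and 725 without CLA replicates 1 and 2 and phenformin replicates 1, 2 and 3.

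Many differences of CLA and of phenformin from LA pointed the same way. Both are taken against the same LA arrays, so a shared response cannot be told here from a difference of those arrays. Of 18193 genes, 2132 were called in the same direction against LA, 1546 higher and 586 lower, and 24 in opposite directions (9 to 32 with 1 array left out). Quantile normalization turned the balance, to 1078 higher and 1355 lower. These 2132 genes made up 58.0% of the genes called with CLA and 62.3% of those called with phenformin. Independent lists of the same sizes would share 314.6 genes higher and 70.4 lower. In simulations all 9 arrays, LA included, were drawn as unchanged independent noise. The simulated groups shared 0 and 0 genes, as calls stay near 0 where nothing is changed, so these counts cannot speak for the overlap. The log2 fold changes correlated across genes at 0.777, against 0.499 in the simulations, which share a control but hold no array-wide difference of LA. Their covariance was 0.221 against 0.0170, a difference of 0.204, and 74.7% of genes had the same sign against 66.7%. Genes are not independent replicates, and with 3 LA arrays the controls could not be split into parts of 2, so part of the excess may come from the shared controls. Without LA replicate 1 and without phenformin replicate 1, 388 and 379 genes were called lower in both. Of the shared genes 262 were also called between phenformin and CLA, 168 with the larger change in CLA and 94 with the larger change in phenformin. Ptgs2, Ccl2 and Atf3 rose in both comparisons and were higher with CLA than with phenformin, whereas Ddit3, Chac1 and Gadd45a rose more with phenformin, as the tests of phenformin against CLA gave.

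**Figure D4:**
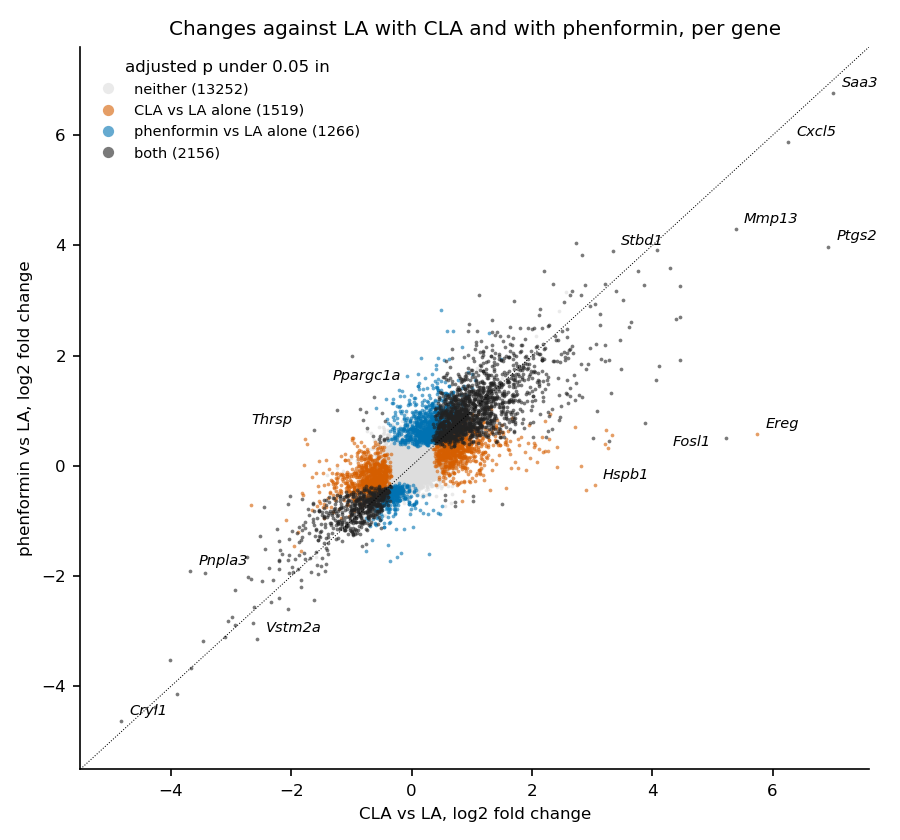
Log2 fold change against LA of each of 18193 genes with CLA (horizontal axis) and with phenformin (vertical axis), with each point a gene. Among genes called in both, 2132 lie in the same direction and 24 in opposite directions. The correlation across genes was 0.777, against 0.499 for simulated groups with a shared simulated control and no effect.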

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

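Chosen after the result was seen were the tests of the spike-in level and of LA replicate 3, the covariate, and the comparison of control transcripts by transcript with a minimum mean difference of 1 on the log2 scale. Control probe sets, which the comparisons left out, gave a higher signal on every treated array than on every LA array, and a mean difference above that minimum, for 6 transcripts in CLA and 4 in phenformin. Beta-actin was higher by 1.511 with CLA and 1.345 with phenformin, and pyruvate carboxylase by 1.377 and 1.390. The spiked bacterial transcripts bioB, bioC and bioD were higher by 2.206, 2.142 and 2.239 with CLA, and bioD by 1.331 with phenformin. The spiked phage transcript cre was higher by 1.371 and 1.001. LA arrays had larger 3' minus 5' differences and weaker signals of these transcripts than the treated arrays, but not of 18S rRNA (9.99 against 9.84 with CLA and 8.70 with phenformin) or the transferrin receptor (4.27 against 4.05 and 4.20).

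If loss of 5' signal set the changes against LA, arrays of a treated group that differ in the pyruvate carboxylase score would show them. The slope would then be at least 0.5, but the larger slope was -0.0197, and the larger slope on the spike-in level was 0.03. The first slope compared replicates 1 and 3, where the pyruvate carboxylase difference was 4.55 and 3.33 in CLA and 4.50 and 3.30 in phenformin. Beta-actin ran the other way there, at 0.515 and 0.632, and at 0.493 and 0.663, so that slope cannot decide on loss of 5' signal. The spike-in slopes compared CLA replicates 1 and 3 again, and phenformin replicates 1 and 2. In each pair the array with the higher spike-in level also had the larger pyruvate carboxylase difference. LA had the lowest mean level but the largest mean difference, so the spike-in slope cannot decide on the amount of labelled target. The total counts did not rest on the narrow range of LA replicate 3, since without that array at least 7620 probe sets were called in each comparison with LA. That array also had the largest SD around the group means (0.256), so leaving it out favours more calls. Without it the share of called probe sets that were higher went from 61.4% to 54.0% with CLA and from 69.8% to 62.2% with phenformin. The balance of directions thus rested in part on that array. With the covariate, which overlaps with the groups and widens the SE, 4895 and 3647 probe sets were called. The 19 of 105 and 29 of 99 called named genes that lost their call went from median sizes of 0.852 and 0.843 to 0.688 and 0.696. The median of their single-gene SEs went from 0.196 and 0.185 to 0.279 and 0.284. The 86 and 70 that kept it went from 2.02 and 1.87 to 1.94 and 1.87. Over the 105 and 99 called named genes the median ratio of sizes was 0.994 and 0.959. Most of the size of these changes was thus left after adjustment for the score. The fit takes the effect of the score only from differences within groups, where the score fell from replicate 1 to 3. Beta-actin ran the other way between those replicates in CLA and phenformin, so these ratios cannot decide on loss of 5' signal. The genes were mostly named for large changes or small p, so they do not stand for all genes. Each group may have been hybridized in its own batch, which cannot be told apart from the treatments here, and the treatments stay the untested biological explanation.

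Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split called 7426, 7401 and 2048 probe sets in CLA vs LA, phenformin vs LA and phenformin vs CLA, and the highest of the other splits called 0, 0 and 0, so 1 split reached each real count. For lists the real counts were 16, 13 and 13 and the highest others 12, 10 and 10.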

How the results depend on the processing

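Chosen after the data were seen were the covariate and the mean of probe sets for the shared genes. Counts are given for CLA vs LA, phenformin vs LA and phenformin vs CLA in this order, and the cause was not tested unless the setting shows it. Requiring at least 2-fold, a stricter rule, left 2613 (1831 higher, 782 lower), 2534 (2060 and 474) and 643 (355 and 288) probe sets, 1227, 1074 and 333 genes, and 639 shared genes (511 and 128). Array weights, which gave LA replicate 3 a weight of 0.312, called 11273, 11123 and 4541 probe sets, with 4965 and 4393 lower in the comparisons with LA, 2906 higher and 1635 lower in phenformin vs CLA, 2428 genes there and 1136 lower in both. The 3' minus 5' covariate gave 4895 probe sets (1572 lower) and 2275 genes for CLA, 3647 (2794 higher, 853 lower) and 1651 for phenformin, and 1144 shared genes (875 and 269). Quantile normalization called 4486 and 4003 probe sets lower against LA and 1355 genes lower in both. It turned Adipoq to -0.31 with CLA and the oxidative phosphorylation medians to -0.19 and -0.048. With an estimated correlation 3, 2 and 2 lists were called. The brown and beige list turned to -0.11 with array weights, -0.053 with quantile normalization and -1.10 without dim probe sets for CLA, and to 0.17 with the covariate for phenformin. Insr in phenformin vs LA was 0.023 over the mean of its probe sets, which disagree.

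Leaving out 1 array at a time gave 4788 to 8313 probe sets for CLA vs LA, 1641 to 3602 lower, 1243 to 2881 lower for phenformin vs LA, and 820 to 3085 for phenformin vs CLA (428 to 1943 higher, 392 to 1142 lower, 463 to 1718 genes). Genes lower in both ranged over 379 to 827, and the brown and beige median for CLA over -0.144 to 0.091. At least once lost were 12 of 105, 12 of 99 and 15 of 68 named gene calls and 4 of 16, 2 of 13 and 5 of 13 list calls. Median centring, the fit of the groups compared alone, the intensity trend and the block moved none of these counts by over 1.5 times. With the replicate number as a block 7486, 7299 and 1761 probe sets were called, of which 6777, 6659 and 1585 were also called without it. Arrays sharing a number had residual correlations of -0.29 to 0.58, and 3 of 18 pairs correlated best with their own number, so the numbers did not meet the bar for pairing, a correlation over 0.1 in every pair. CLA and phenformin arrays of one number correlated at 0.29, 0.0925 and 0.582, and the pyruvate carboxylase 3' minus 5' difference fell from replicate 1 to 3 in each group, so a shared pattern stays open there. The probe sets of Cryl1, E2f5, Depp1, Nrip2 and Aif1l were highest in replicate 3 of every group, LA included. The block ended 3, 2 and 2 named gene calls (Cd14, Dio2 and Ppargc1a, then Adgre1 and Cd14, then Lss and Mcm3) and added the insulin signalling list in phenformin vs CLA (adjusted p = 0.0415). The filter on dim probe sets kept 23938 of 45037, and signal near background limits what the others can show.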

Other observations

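Chosen after the result was seen were the tests of disagreeing probe sets and of 5' loss among the largest falls, the Fisher's exact test of the rises, the test of the spike-in level, the use of different LA arrays, the opposite genes with each array left out, and the genes named here outside the fixed rule.

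Few genes moved in opposite directions with CLA and phenformin. Of the 24 such genes 17 were lower with CLA and higher with phenformin and 7 the reverse. With 1 array left out 9 to 21 of them stayed opposite, and 7 did so whichever array was left out: Cdo1, Klb, N4bp2l1, Ppp1r3b, Taf15, Tex19.1 and Thrsp. Klb, the coreceptor of fibroblast growth factor signalling in fat, had -0.86 ± 0.16 with CLA and 1.04 ± 0.16 with phenformin. Ppp1r3b, which targets a phosphatase to glycogen, had -0.76 ± 0.14 and 0.98 ± 0.14, and Thrsp -1.62 ± 0.12 and 0.65 ± 0.12. Cdo1, a cysteine dioxygenase, had -0.65 ± 0.12 and 0.54 ± 0.12. Taf15, an RNA-binding protein, had -0.99 ± 0.20 and 2.001 ± 0.20. These genes had limma adjusted p under 0.05 in both comparisons, and the other probe sets of Taf15 and Klb were not called in phenformin vs CLA. Of the 7 reverse genes, such as Angptl4, Ripk3, Cd14 and Dnajb1, only Tex19.1 stayed opposite throughout.

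Among the largest falls against LA, 4 of the 7 genes with further probe sets had none called lower: Aif1l, Cryl1, E2f5 and Nrip2. For Cryl1 the brightest probe set had -4.82 with CLA and the others -0.06, -0.05 and -0.14. A candidate explanation is that these probe sets measure something other than the named gene as a whole. Loss of 5' signal would make them rise with the pyruvate carboxylase 3' minus 5' score within groups. The median correlation with that score was -0.672 (range -0.78 to -0.271). This cannot decide on 5' loss, since all 4 were highest in replicate 3 of every group, where that score was lowest. In replicates 1, 2 and 3, Cryl1 was at 10.5, 9.50 and 12.1 in LA and at 5.53, 5.25 and 6.88 in CLA. In replicate 3 beta-actin had its largest difference within CLA (0.632) and phenformin (0.663), but its smallest within LA (0.981). Of the 2 genes among the largest rises with further probe sets, 0 had none called higher, which is too few for a comparison.

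The overlap of CLA and phenformin may reflect a shared response, the shared LA arrays or a technical difference of those arrays. With different LA arrays behind the comparisons the correlation of log2 fold changes ranged from 0.5264 to 0.7436, and values under 0.2 had been set, before it was computed, as the mark of shared controls. Of 100 splits of the 9 arrays into a control and 2 groups, the real one included, only the real one reached 2132 genes, which argues against chance. The next 3 splits, with 1773, 1506 and 1498 genes, also kept the LA arrays as control and mixed CLA with phenformin arrays. The count therefore mostly reads how LA differs from the treated arrays and cannot by itself show a shared response. Slopes within treated groups were at most -0.0197 on the 5' score and 0.03 on the spike-in level. The spike-in slope cannot decide on the amount of labelled target. In the arrays compared, a higher spike-in level went with a larger pyruvate carboxylase difference, whereas LA had the lowest level and the largest difference. The 5' slope cannot decide either, since beta-actin ran the other way in the arrays compared. A shared response therefore stays open beside a difference of the LA arrays, such as RNA or target quality, target amount or a batch.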
